A study of Arabidopsis thaliana with 3 samples.

How the data were processed

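RNA from whole Arabidopsis thaliana seedlings was compared on 3 two-colour Agilent oligonucleotide arrays. Per the labels, each array carried Cy3-labelled RNA of the Col-0 wild type and Cy5-labelled RNA of the ila3 mutant, from plants grown on plates for 20 days after sowing. Per the labels, 0.5 µg of RNA was amplified and labelled for each sample. The series describes the replicates as biological. The dyes were in the same orientation on every array, so dye and genotype cannot be told apart by the design. All arrays were on the same slide, so slide and scan could not act as batches.

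The deposited scanner files hold, per the file headers, unnormalized spot intensity in each channel, given as the mean pixel brightness of the spot and the median of its local background, from Agilent Feature Extraction 9.5.1 per the submitters' processing notes. They also hold, per the file headers, the log10 ratio of Cy5 over Cy3 after the software's own background subtraction and dye normalization. The authors' processed value table, as deposited, holds log2 ratios of Cy5 over Cy3 for 29554 probes per array, which the authors normalized and centred near 0. Set against the scanner's ratios of the same array, converted to log2, its columns had the same direction, with correlations across probes of 0.959, 0.953 and 0.887 and medians of -0.04, -0.02 and 0.003. The kind of normalization, and how its probes were chosen, are not given in the sources used here. Against the ratios derived below from the intensities, the columns of the authors' table correlated less well, at 0.911, 0.863 and 0.713 on replicates 1, 2 and 3. Every value column of that table was used, so 0 were left aside.

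From the intensities, the background was corrected by the normexp method with an offset of 50, and each array was normalized by loess, with control spots at weight 0 and no scaling between arrays, in limma 3.58.1 under R 4.3.3. Spots marked as non-uniform or as population outliers in either channel, 9 to 25 per array, were set to missing. Spots of a probe were averaged. A probe was kept if it was well above background in the same channel on at least 2 arrays and measured on at least 2, which left 29822 probes. Ratios are log2 of ila3 over wild type, so positive values are higher in ila3. Of 43603 probes on the array, 34617 were named through a RefSeq accession in the supplied gene table, 1962 by the locus in the array file and 239 by symbol, and 6785 had no locus. Each locus was represented by its brightest kept probe. This gave 19484 genes, of which 5967 had more than 1 kept probe. Symbols are those of the supplied gene table, and older names appear where that table gives them.

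Each gene's mean ratio was tested against 0 with limma's lmFit and eBayes and Benjamini-Hochberg adjustment over all genes, called at an adjusted p of 0.05. The SD given with a ratio is over arrays. Gene lists, and the alternatives tried below, were fixed before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 30 lists with at least 4 tested members. Camera with an estimated correlation and fry were run beside it. With 3 arrays, camera with an estimated correlation has few degrees of freedom and so little power. The ribosomal protein lists were drawn from the array file's descriptions alone, because the supplied gene table holds no descriptions. The lists of plastid and mitochondrial genome loci matched 0 loci, and the seed maturation list had 3 tested genes, with a mean log2 ratio of -0.02 and a median of 0.004, too few for the test.

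The genes named are the 10 largest rises and 10 largest falls among called genes with the same sign on all 3 arrays, ILA, GCN2 and GCN20, up to 4 members of smallest p of each called list, and up to 2 of each other list described. Any gene singled out beyond this rule is said to have been chosen after its values were seen. The fit was tested on simulated data for the comparison of ila3 with wild type. With 19484 genes and 200 changed, 78.0% of 100 genes changed 2-fold and 99.0% of 100 genes changed 4-fold were recovered, and 6.84% of calls were false. The simulated changes were in genes brighter than the median and of the same size on every array, with no gene-specific dye effect. The real arrays differ in this, so these rates need not hold for them. The alternatives tried were the background correction, the software's own ratios, median centring, scaling between arrays, the filter on dim probes, the marked spots, averaging of probes, the variance model, a test against a fold of 1.2, separate channels without pairing by array, the authors' value table and leaving out each array. The number of arrays limits the precision, and replicate p-values measure only the spread between these 3 arrays.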

Results

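Transcript levels were measured in seedlings of the ila3 mutant and of the Col-0 wild type, the Arabidopsis reference accession, on 3 arrays, each with 1 biological replicate of both genotypes. The comparison asked which transcripts differed between mutant and wild type. Of all probes, 65.8% to 91.8% were well above background in the ila3 channel and 64.7% to 84.97% in the wild-type channel. The ratios of different arrays correlated across genes with Pearson coefficients of 0.852 for replicates 1 and 2, 0.840 for 1 and 3 and 0.801 for 2 and 3, over genes, which are not independent replicates. The spread of the log2 ratios was 0.44 on replicate 1, 0.55 on replicate 2 and 0.25 on the array labelled replicate 3.

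In ila3 seedlings, genes for ribosomal proteins of the cytosol and of organelles, for building the chloroplast, for heat shock and for flavonoid synthesis were higher as lists, and genes of salicylic acid defence, of abscisic acid, cold and drought responses, of senescence and of the cell cycle were lower. These 9 calls, 5 higher and 4 lower, come from camera with a preset correlation, and none held with an estimated correlation (adjusted p = 0.758 for each) or with fry, whose smallest adjusted p was 0.0574. The test with an estimated correlation called 0 lists under every setting that tested lists. For heat shock that correlation was -0.05, below the preset 0.01, yet the unadjusted camera p rose from 0.00402 to 0.0916. Failing that test with 3 arrays therefore says little about any list. The largest rise was in AT2G21640, at a log2 ratio of 3.28 ± 2.11 (SD, n = 3), and the largest fall in AT3G55240, at -4.10 ± 1.11 (SD, n = 3). ILA, the gene the mutant is taken to be named for, was far lower in ila3 on replicates 1 and 2 but not on the array labelled replicate 3.

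ILA (ILITHYIA, AT1G64790), a homologue of the yeast translational regulator GCN1 was linked to the mutant's name from general knowledge, not from the labels. Its log2 ratio was -3.33 on replicate 1 and -3.50 on replicate 2, but 0.40 on the array labelled replicate 3. The mean of -2.15 ± 2.205 (SD, n = 3) did not pass the test (limma adjusted p = 0.105), whereas without replicate 3 it was -3.42 with an adjusted p of 1.06e-04, in a range of 1.06e-04 to 0.365 over all alternatives. The probe lay on chromosome 1 at 24065246 to 24065594, in the coordinates of the older genome build that the array file names (ath1:Jan2004), and a second probe at 24066837 to 24066990 gave -1.14, -0.97 and 0.12. Neither probe was well above background in the ila3 channel on replicate 2, so the ratios of that array, -3.50 and -0.97, are imprecise. ILA therefore goes against the label of 1 library, written below as the library labelled ila3 replicate 3. The site of the ila3 lesion is not given in the sources used here, so whether the probes lie in an altered part is open. GCN2 (AT3G59410), the kinase that GCN1 activates, had a ratio of 0.08 ± 0.01 (SD, n = 3; limma adjusted p = 0.351), and ABCF3 (AT1G64550), the homologue of GCN20, had 0.18 ± 0.50 (SD, n = 3; limma adjusted p = 0.505). Without replicate 3 ABCF3 stood at 0.46 and passed (adjusted p = 0.0209, in a range of 0.0209 to 0.978 over all alternatives), and without replicate 2 it stood at -0.0094.

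**Figure D1:**
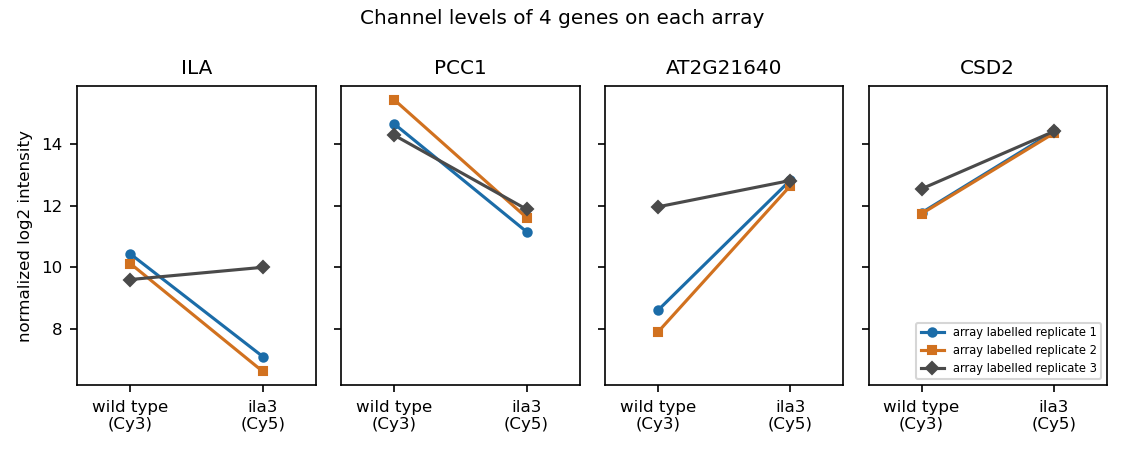
Normalized log2 intensity (vertical axis) of 4 genes in the wild-type (Cy3) and ila3 (Cy5) channels, 1 line per array. ILA falls from wild type to ila3 on replicates 1 and 2 and is at 9.60 and 9.998 on the array labelled replicate 3, while PCC1, AT2G21640 and CSD2 move in the same direction on every array.

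Of 19484 genes tested, 2725 were higher and 2486 lower in ila3 at an adjusted p below 0.05 (limma). Of these, 302 were at least 2-fold higher and 195 at least 2-fold lower, and the median size of a called change was 0.51 on the log2 scale. Every call lay near the threshold, since the smallest limma adjusted p of any gene was 0.0332, and a cutoff below that value would call no gene. Many genes share that value, so it does not rank them. The smallest adjusted p was 0.0492 with the software's own ratios and 0.0449 with the authors' values. The sign was the same on all 3 arrays for 5210 of the 5211 called genes. Passing the test with 3 arrays nearly requires this, so it is no separate support. Single arrays decided the counts of called genes. Without replicate 1, 0 genes passed in either direction, although 4855 had an unadjusted p under 0.05 against 8789 with every array; without replicate 2, 608 were higher and 688 lower, of which 80 and 103 were at least 2-fold; and without the library labelled ila3 replicate 3, 3218 were higher and 2941 lower, of which 564 and 342 were at least 2-fold. Tested against a fold of 1.2, 0 genes passed, with 3190 at an unadjusted p under 0.05. Every array had ila3 in Cy5, so an effect of the dye could not be separated from genotype.

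The largest rise was in AT2G21640, a gene known as a marker of oxidative stress in mitochondria, at 3.28 ± 2.11 (SD, n = 3; limma adjusted p = 0.0412). EMB2729, annotated as an amylase-like enzyme, rose by 2.58 ± 1.36, ANAC087, a NAC transcription factor, by 2.38 ± 1.299, and CSD2, the chloroplast copper/zinc superoxide dismutase, by 2.38 ± 0.44. AT5G51440, a mitochondrial small heat shock protein, rose by 2.32 ± 1.21, AT2G18193, an AAA-type ATPase, by 2.24 ± 1.14, and RHL41, the zinc finger protein also called ZAT12, by 2.09 ± 0.72. AT3G49320, AT5G60250, a RING finger protein, and AT3G58270, a protein with a meprin and TRAF homology domain, rose by 2.40, 2.39 and 2.09. The largest fall was in AT3G55240, at -4.10 ± 1.11 (SD, n = 3; limma adjusted p = 0.0332). AT3G22235 and AT3G22240 followed at -3.98 ± 1.05 and -3.92 ± 1.04. The neighbouring gene PCC1, known to respond to pathogens and the circadian clock, fell to -3.25 ± 0.75, and LURP1, known to be induced by the downy mildew pathogen, to -3.62 ± 1.11. BG3, a beta-1,3-glucanase, stood at -2.59 ± 1.22, AT5G03350, a legume lectin protein, at -2.61 ± 0.75, AT4G13575 at -3.05, UNE15 at -2.52 and AT2G25510 at -2.44. AT5G60250, AT5G51440 and AT2G18193 were well above background in the wild-type channel on 2 of the 3 arrays, and AT4G13575 and BG3 in the ila3 channel on 2, so their ratios and their places among the largest changes are imprecise. Apart from RHL41, the change in each of these genes was smallest on the array labelled replicate 3. Limma's adjusted p was 0.0332 to 0.0412 for all of them, and none passed without replicate 1, where the smallest adjusted p of any gene was 0.183.

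**Figure D2:**
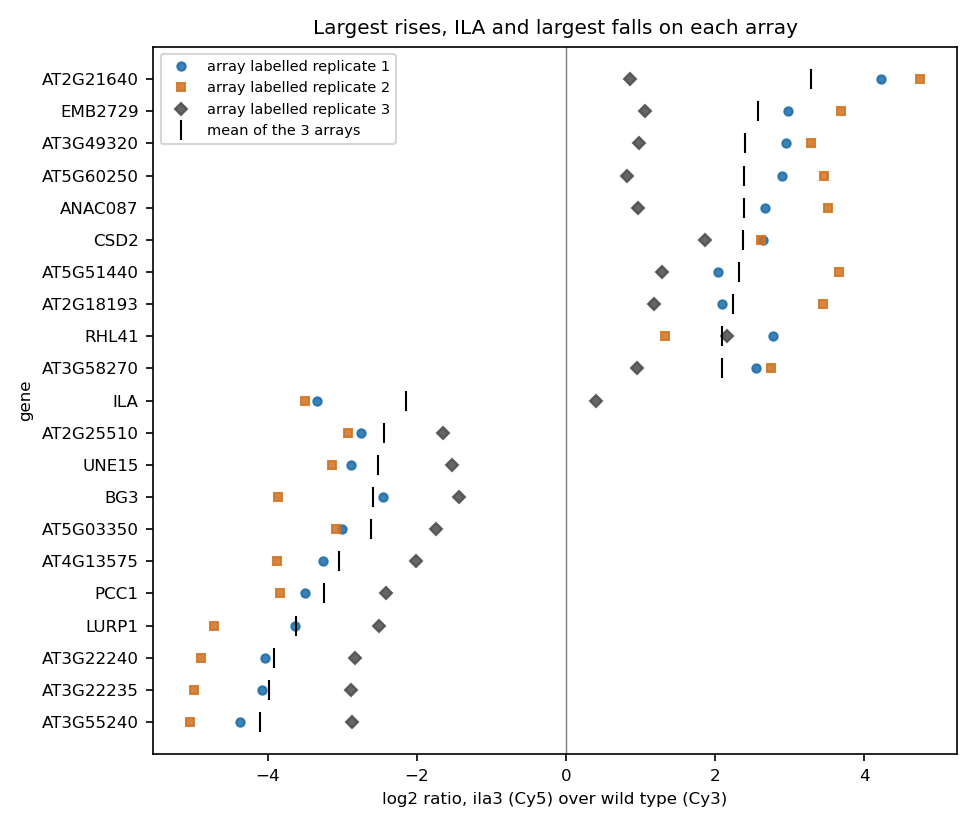
Log2 ratio of ila3 over wild type (horizontal axis) on each of the 3 arrays for the 10 largest rises, ILA and the 10 largest falls, with the mean as a bar. AT2G21640 stands at 4.23 and 4.75 on replicates 1 and 2 and at 0.86 on the array labelled replicate 3. The rises and falls drawn were chosen for having the same sign on every array, and ILA was not.

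Of 184 cytosolic ribosomal protein genes tested, 44 rose and 0 fell, with a mean log2 ratio of 0.42 ± 0.26 (SD over genes) and a camera adjusted p of 2.17e-13; adjusted over the list alone, 0 passed. Among them AT5G62300, a small subunit protein S20, rose by 0.93 ± 0.34, AT4G13170, a large subunit protein L13A, by 0.88 ± 0.38, AT4G39200 by 0.79 ± 0.32 and AT2G40510 by 0.68 ± 0.28. Of 17 nuclear genes for organellar ribosomal proteins, 13 rose and 0 fell, with a mean of 0.48 ± 0.31 and a camera adjusted p of 2.69e-05; adjusted over the list alone, 15 rose. RPL21C, a plastid large subunit protein, rose by 1.06 ± 0.24, a lower limit because its ila3 channel was saturated on 1 array, PSRP5 by 0.97 ± 0.35, PSRP6 by 0.83 ± 0.17 and EMB3137 by 0.49 ± 0.13. Neither call held with an estimated correlation (adjusted p = 0.758 for both). Without replicate 2 the cytosolic mean was 0.23, and without replicate 1 no single gene passed (smallest limma adjusted p 0.183).

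Of 26 genes for building the chloroplast, 16 rose and 3 fell, with a mean of 0.45 ± 0.65 and a camera adjusted p of 0.00127; adjusted over the list alone, 18 rose and 4 fell. CPN60B, a chaperonin subunit, rose by 1.05 ± 0.35, the chaperone cpHsc70-1 by 0.98 ± 0.35 and TOC159, a receptor for protein import, by 0.88 ± 0.34. GPRI1, the transcription factor also called GLK1 that drives photosynthetic genes, moved the other way, to -1.48 ± 0.51. Of 15 heat shock genes, 5 rose and 0 fell, with a mean of 0.34 ± 0.51 and a camera adjusted p of 0.0134; adjusted over the list alone, 7 rose and 1 fell. HSP70 rose by 1.85 ± 0.76, AT1G59860 by 0.82 ± 0.37, HSP90.1 by 0.68 ± 0.35 and the factor HSFA2, above background in the wild-type channel on 2 of the 3 arrays, by 0.49 ± 0.22. This call ended without the library labelled ila3 replicate 3 (adjusted p = 0.0513, in a range of 0.00234 to 0.0565 over all alternatives). Of 16 flavonoid and anthocyanin genes, only PAL1, the first enzyme of phenylpropanoid synthesis, passed, at 0.48 ± 0.17, as it did adjusted over the list alone. The list's mean was 0.24 ± 0.15 with a camera adjusted p of 0.00719, and TT4, F3H and PAP1 had ratios of 0.47, 0.37 and 0.36 (limma adjusted p = 0.0554, 0.0661 and 0.0794). PAP1 was above background in the wild-type channel on 2 of the 3 arrays and stood at 0.21 without replicate 2. Without replicate 2 the list's mean was 0.14, and without replicate 1 no single gene passed (smallest limma adjusted p 0.183). None of these 3 calls held with an estimated correlation (adjusted p = 0.758 for each).

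Salicylic acid defence genes were lower in ila3. Of 21 tested, 11 fell and 0 rose, with a mean of -0.92 ± 0.81 and a camera adjusted p of 2.38e-06; adjusted over the list alone, 17 fell. PCC1 stood at -3.25, ACD6, a regulator of cell death and defence, at -2.36 ± 1.01, BGL2, the pathogenesis-related glucanase PR2, at -1.93 ± 0.77, and AT5G52810 (SARD4), an enzyme of pipecolic acid synthesis, at -1.39 ± 0.42. Of 22 abscisic acid, cold and drought genes, 10 fell and 0 rose, with a mean of -0.44 ± 0.59 and a camera adjusted p of 5.82e-04; adjusted over the list alone, 12 fell. RAB18 stood at -1.72 ± 0.61, KIN1 at -1.33 ± 0.19, KIN2 at -1.12 ± 0.21 and COR15B at -0.96 ± 0.30. No single gene passed without replicate 1 (smallest limma adjusted p 0.183). Neither call held with an estimated correlation (adjusted p = 0.758 for both).

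Of 11 senescence and starvation genes, 5 fell and 0 rose, with a mean of -0.65 ± 0.64 and a camera adjusted p of 0.00614; adjusted over the list alone, 5 fell. The transcription factor NAC6, also called ORE1, stood at -1.62 ± 0.50, the asparagine synthetase ASN1 at -1.40 ± 0.26, NAP at -0.99 ± 0.21 and ACD1, the chlorophyll breakdown enzyme PAO, at -0.58 ± 0.18. Of 18 cell cycle genes, 5 fell and 0 rose, with a mean of -0.32 ± 0.24 and a camera adjusted p of 0.00263; adjusted over the list alone, 5 fell. The named members act in DNA replication: MCM2 stood at -0.76 ± 0.34, the clamp PCNA1 at -0.60 ± 0.26, CDC45 at -0.55 ± 0.30 and MCM5 at -0.53 ± 0.24. Without replicate 1 the cell cycle mean was -0.18 and no single gene passed (smallest limma adjusted p 0.183). Neither call held with an estimated correlation (adjusted p = 0.758 for both).

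**Figure D3:**
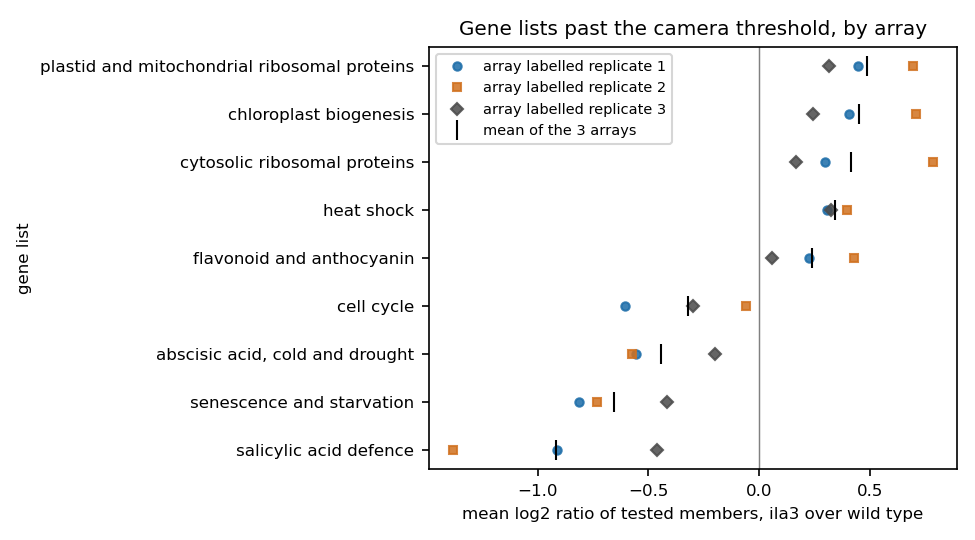
Mean log2 ratio of the tested members (horizontal axis) of the 9 gene lists past the camera threshold, on each of the 3 arrays and as the mean over arrays. Cytosolic ribosomal proteins average 0.42 and salicylic acid defence genes -0.92, and each list lies on the same side of 0 on every array.

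The photosynthesis lists did not pass. Of 18 light harvesting genes, 2 rose and 3 fell (camera adjusted p = 0.332); adjusted over the list alone the counts were also 2 and 3. The antenna genes LHCB2.3 and LHCB4.3 fell, at -2.04 ± 0.16 and -1.10 ± 0.18. The list's mean of -0.22 turned to 0.0016 with median centring and to 0.23 in the authors' value table. Of 28 photosystem and electron transport genes, 2 rose and 6 fell (camera adjusted p = 0.0781), also when adjusted over the list alone. NPQ4, the PsbS protein of energy dissipation, fell to -1.41 ± 0.31 and PSAH2 to -0.82 ± 0.24. The list's mean of -0.16 turned to 0.0602 and 0.17 under the same settings. With the probes of a gene averaged, both lists were called lower, at -0.47 (adjusted p = 4.61e-05, in a range of 4.61e-05 to 0.415 over all alternatives) and -0.28 (adjusted p = 5.98e-04, in a range of 5.98e-04 to 0.157). Both were also called lower with the software's own ratios, at -0.34 and -0.26, and higher in the authors' value table (adjusted p = 0.00623 and 0.0391), and the photosystem list was called lower with no background subtraction, at -0.19, and without the filter on dim probes, at -0.16 (adjusted p = 0.0344 and 0.0312). None of these calls held with an estimated correlation (adjusted p = 0.741 for averaged probes, 0.668 for the software's ratios, 0.768 and 0.869 for the authors' values, and 0.731 and 0.718 for the photosystem list's other calls). Of 18 Calvin cycle genes, 4 rose and 3 fell, both over all genes and adjusted over the list alone (camera adjusted p = 0.897). The list's mean of 0.02, median of -0.09 and camera direction, which was down, differed in sign, and with median centring the list was called at 0.22 (adjusted p = 0.0115, in a range of 0.0115 to 0.983), but not with an estimated correlation (adjusted p = 0.692). CP12-2 fell to -1.30 ± 0.26 and GAPB rose by 0.90 ± 0.16. Of 18 chlorophyll synthesis genes, 2 rose and 1 fell (camera adjusted p = 0.280), with 1 and 0 adjusted over the list alone. With median centring this list was called, at 0.15 (adjusted p = 0.00675, in a range of 0.00675 to 0.592), but not with an estimated correlation (adjusted p = 0.692). The cyclase gene CRD1 rose by 0.55, a lower limit because its ila3 channel was saturated on 2 arrays, PORA, a protochlorophyllide reductase, fell to -1.27 ± 0.80, and the list's mean of 0.05 was -0.0058 without replicate 2. No single gene passed without replicate 1 (smallest limma adjusted p 0.183).

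Oxidative stress genes went both ways, with 8 of 18 rising and 6 falling (camera adjusted p = 0.341) and 9 and 6 adjusted over the list alone. CSD1, the cytosolic copper/zinc superoxide dismutase, rose by 1.16 ± 0.11. Of 19 jasmonate and ethylene genes, 3 fell and 0 rose (camera adjusted p = 0.323), with CORI3 at -1.65 ± 0.58 and VSP2 at -1.86 ± 1.09; adjusted over the list alone, 1 fell. Of 14 auxin genes, 1 rose and 4 fell (camera adjusted p = 0.0781), also adjusted over the list alone, with DFL1, an auxin-conjugating enzyme, at -0.96 ± 0.03; with the software's own ratios this list was called, at -0.39 (adjusted p = 0.0457, in a range of 0.0457 to 0.135), but not with an estimated correlation (adjusted p = 0.668). Of 13 cell wall expansion genes, 1 rose and 4 fell (camera adjusted p = 0.0861), or 2 and 5 adjusted over the list alone, with EXPA11 at -0.84 ± 0.24 and XTH4 at -0.69 ± 0.10; this list was called without the filter on dim probes and without replicate 3, the latter at a mean of -0.34 (adjusted p = 0.0342, in a range of 0.0342 to 0.268 over all alternatives). Of 27 amino acid synthesis genes, 5 rose and 1 fell (camera adjusted p = 0.228), also adjusted over the list alone. ATP-PRT1, the first enzyme of histidine synthesis, rose by 0.76 ± 0.26, and GS2, the plastid glutamine synthetase, fell to -1.38 ± 0.19. Of 16 aliphatic glucosinolate genes, 1 rose and 4 fell (camera adjusted p = 0.228), also adjusted over the list alone, and this list too was called without replicate 3, at a mean of -0.33 (adjusted p = 0.0326, in a range of 0.0326 to 0.584). Neither that call nor those of the cell wall list held with an estimated correlation (adjusted p = 0.724 without replicate 3 for both lists and 0.718 without the filter on dim probes). No single gene passed without replicate 1 (smallest limma adjusted p 0.183).

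The morning clock list had 2 of 6 genes rising (camera adjusted p = 0.0781), with CCA1 at 0.78 ± 0.35 and PRR7 at 0.58 ± 0.15, and the evening clock 1 of 7, PRR5, at 0.64 ± 0.16 (camera adjusted p = 0.388). The morning clock list was called with the software's own ratios, at 0.47 (adjusted p = 0.0288, in a range of 0.0288 to 0.157), and also without the filter on dim probes and in the authors' value table, but in none of these with an estimated correlation (adjusted p = 0.668, 0.718 and 0.768). Pattern-triggered immunity had 4 of 14 genes falling (camera adjusted p = 0.228), among them the flagellin receptor FLS2 at -0.42 ± 0.19 and its partner BAK1 at -0.34 ± 0.15, and the list's mean of -0.09 was 0.0705 without replicate 2. Autophagy had 1 of 12 genes rising and 3 falling (camera adjusted p = 0.308), with APG8A at -0.60 ± 0.20 and ATG8F at -0.59 ± 0.13. Iron deficiency had 2 of 8 genes falling (camera adjusted p = 0.228), FRU at -0.69 ± 0.41 and the reductase FRO3 at -0.51 ± 0.12, and phosphate starvation 3 of 12 (camera adjusted p = 0.414), with MGD2 at -0.57 ± 0.24. Adjusted over the list alone, 2 autophagy genes rose and 4 fell, 1 phosphate starvation gene rose and 3 fell, and the counts of the clock, immunity and iron lists were the same as over all genes.

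In the GCN1 pathway list 1 of 5 genes rose, or 2 adjusted over the list alone (camera adjusted p = 0.341). That gene was AT2G40290, a subunit of translation initiation factor eIF2, at 0.66 ± 0.34. The list's mean was -0.18, but its median was 0.18 and camera's direction was up. ILA itself, at -2.15, was the only negative member, so it alone made the mean negative. The list's mean was -0.07 without replicate 1 and -0.32 without replicate 3. No member of the unfolded protein response (13 tested), indole glucosinolate (7 tested) or flowering lists (7 tested) passed the limma test, also adjusted over the list alone, with camera adjusted p-values of 0.833, 0.897 and 0.747. The unfolded protein response had a mean of 0.0068 and a median of -0.0038, with camera's direction up; its mean was -0.0858 without replicate 2, where that of indole glucosinolates, -0.04 with every array, was 0.0526. Of 10 root markers, 1 fell, SHR at -0.44 ± 0.17, also adjusted over the list alone (camera adjusted p = 0.833), and the list's mean of 0.0022 was -0.0224 without replicate 1 and -0.0094 without replicate 2. No single gene of these lists passed without replicate 1 (smallest limma adjusted p 0.183).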

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

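The tests in this part were chosen after the results they concern were seen, except those of the sign splits. Probes that no locus names were outside the comparisons above. Of 2551 such probes tested with all 29822 kept probes, 156 were higher and 197 lower in ila3 at an adjusted p below 0.05 (limma).

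The ratios on the array labelled replicate 3 were smaller than on the others. Over 561 genes changed at least 2-fold in the same direction on replicates 1 and 2, its ratio followed theirs with a slope of 0.435, or 0.391 for rises and 0.489 for falls. A compressed measuring scale is argued against by the spike-in controls, whose observed log ratios followed the expected ones with a slope of 0.897 on that array, against 0.813 on the lowest of the others. RNA like that of ila3 mixed at a single share into the wild-type channel gave a fitted share of 0.579, but 0.463 from rises and 0.689 from falls alone. The bootstrap bounds of that difference, -0.254 to -0.196, are over genes, which are not independent, and give no spread between arrays. Choosing genes on replicates 1 and 2 also lowers the replicate 3 ratio and so raises the fitted shares. Whether it does so unequally for rises and falls was not tested, so its part in the difference is unknown. Taken alone, the difference speaks against a single share, whereas the channel positions given below do not. The residual SD of the curve and of a straight line did not separate them (bounds of the difference -0.0126 to 0.0153). Channel levels depend on the scaling between arrays. On their linear scale, the wild-type channel of that array lay between wild type (0) and ila3 (1). Its median position was 0.454 for rises (quartiles 0.374 to 0.550) and 0.488 for falls (0.413 to 0.549). A single share of ila3-like RNA would put rises and falls at the same position on that scale. These positions therefore do not argue against such a mixture, which stays open. Wild-type plants of that replicate in an intermediate state stay open too and were not tested.

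ILA was not lower in the library labelled ila3 replicate 3. Exchanged channels on that array are argued against by the lower of its correlations with the other arrays, 0.801 across genes, and a defective spot by the second ILA probe, at 0.12 there. Wild-type RNA in the ila3 channel is argued against by the position of the 561 genes between wild type (0) and ila3 (1), a median of 0.942 on that array, where ILA lay at 0.1998; in the wild-type channel ILA lay at 0.417, near the median of 0.469 of those genes. Of 40 genes changed at least 4-fold on both other arrays, 1 had the opposite sign there, which was ILA. A candidate explanation is plant material with another lesion or another state of ILA in that library, which no biological group of the design tests.

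Dye and genotype are confounded in every called gene. A dye effect specific to a probe's sequence is argued against, as the source of a change's direction, by the second probes of called genes. These had the same sign in 97.3% of 182 genes changed at least 2-fold and 93.5% of 1683 changed less. The size held less well, since the second probe's ratio was at a median of 0.745 and 0.671 of the first's. A dye effect of fixed size on each transcript is argued against, for most changes large on replicates 1 and 2, by the median of 0.404 between the replicate 3 ratio and the mean of the other arrays over the same 561 genes, a choice of genes that itself lowers the ratio. Over the 497 called genes changed at least 2-fold, chosen on all arrays, the median was 0.426 (quartiles 0.351 to 0.560). In those genes the replicate 2 ratio was at a median of 1.74 of the others. Over 105 genes chosen on replicate 3 alone, which raises it, the median was 0.710 (bootstrap bounds 0.656 to 0.776), with quartiles of 0.574 to 1.17. Those quartiles reach the value that a fixed effect would give. For genes large on replicate 3, a dye effect of fixed size therefore stays open. For changes under 2-fold it cannot be told apart from genotype, since 0 arrays had the dyes exchanged.

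With 3 arrays there are 4 sign splits, too few for a share under 0.05. As labelled, 5211 genes were called by limma, against 0 in the highest of the others. Those splits had 7 to 83 genes at an unadjusted p under 0.05, fewer than the 974 expected by chance. For changes of at least 2-fold the numbers called were 497 and 0. The arrays' ratios correlated at 0.801 to 0.852, so turning 1 array cancels shared changes and 0 calls say little. A dye effect shared by all arrays would give the same contrast. For gene lists, 9 were called as labelled and 12 in the highest of the others, with replicate 3 turned, so 2 of the 4 splits called as many lists and 1 as many genes.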

How the results depend on the processing

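No alternative in this part was chosen after the results were seen. The 9 called gene lists kept their direction under every alternative run, with the flavonoid list past the threshold except with separate channels (adjusted p = 0.0739, in a range of 0.0024 to 0.0739) and the heat shock list except with separate channels, the strict filter and without replicate 3. Leaving out each replicate in turn gave 0 to 3218 higher and 0 to 2941 lower genes, 0 to 564 and 0 to 342 at least 2-fold (limma; the 0 is without replicate 1, with 4855 at an unadjusted p under 0.05), an ILA ratio of -3.42 to -1.47 (-3.45 with the authors' values to -1.22 with scaling between arrays over all alternatives), and 4 to 5 lists higher and 4 to 6 lower. With a variance trend and robust moderation 4839 genes were higher and 4989 lower, and ILA at -2.15 passed (adjusted p = 0.0173, in a range of 1.06e-04 to 0.365). Against a fold of 1.2, 0 genes were higher or lower, with 3190 at an unadjusted p under 0.05; that test asks for more by construction. With separate channels and no replicate block, which drops the pairing by array, 1548 genes were higher and 1321 lower, and 3 lists higher. The software's own ratios gave 1495 higher genes, 435 at least 2-fold lower and 7 lists lower. With the authors' values 517 genes were at least 2-fold higher, 472 at least 2-fold lower and 8 lists higher; the cause was not tested. Counts of similar size need not be the same genes. Of the 5211 genes called in the main fit, 54.8% were also called with the software's own ratios and 65.3% with the authors' values. The share was 54.3% with separate channels and 23.5% without replicate 2. Under the other settings that called any gene it was 83.7% to 99.96%. With both channels above background on every array ILA left the tested genes, so that setting gives no ILA value. Signal over background limits the dim genes, since 64.7% of probes on replicate 2 were well above background in the wild-type channel.

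Among called genes PETC, chosen after its values were seen, was called at 0.35 and, with probes averaged, at -0.28. Called genes outside the named ones were checked for a changed sign only where the alternative called them too. Among the named genes and the lists, the values that changed sign belong to those not called in the report. The cause was not tested. ABCF3 turned to -0.0848 with scaling between arrays and AG to 0.0654 without the dim filter. The GCN1 pathway list, without ILA under the strict filter, turned to 0.32. Median centring turned light harvesting to 0.0016, photosystems to 0.0602 and root markers to -0.0249, and the authors' values turned light harvesting to 0.23, photosystems to 0.17, chlorophyll synthesis to -0.0625 and the unfolded protein response to -0.0804. No background subtraction turned the Calvin cycle to -0.0017 and the unfolded protein response to -0.0052. The software's ratios turned the Calvin cycle to -0.0622, chlorophyll synthesis to -0.0738 and the unfolded protein response to -0.0940. Averaging probes turned the Calvin cycle to -0.17 and the unfolded protein response to -0.0112. Scaling between arrays turned indole glucosinolates to 0.0308 and root markers to -0.0357, and the strict filter root markers to -0.12. Leaving out each replicate gave -0.0094 to 0.46 for ABCF3, -0.0058 to 0.0885 for chlorophyll synthesis, -0.1751 to 0.0705 for pattern-triggered immunity, -0.1128 to 0.0526 for indole glucosinolates, -0.0858 to 0.0922 for the unfolded protein response and -0.0224 to 0.0384 for root markers. Of the other named-gene values under the alternatives, 1154 kept direction and side of the threshold, 179 lost the call and 28 gained it; of list values, 377 kept both, 4 lost the call and 15 gained it.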

Other observations

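The gene families and genes in this part were chosen after the data were seen. Families named by the array's descriptions, 16 in all, were set against all other genes with camera. Pentatricopeptide repeat proteins, which process organellar RNA, had 133 of 343 genes rising and 0 falling, with a mean log2 ratio of 0.36 (camera adjusted p = 2.34e-18). Aminoacyl-tRNA synthetases had 31 of 53 rising and 2 falling, with a mean of 0.42 (3.54e-10), RNA helicases 17 of 39 rising and 0 falling, with a mean of 0.38 (3.06e-08), and translation initiation factors 22 of 69 rising and 1 falling, with a mean of 0.26 (4.28e-05). Glutathione S-transferases had 10 of 34 falling and 0 rising, with a mean of -0.36 (3.73e-04), histones 17 of 33 falling and 1 rising, with a mean of -0.29 (4.01e-04), peroxidases 16 of 53 falling and 1 rising, with a mean of -0.25 (0.00132), and receptor kinases 41 of 184 falling and 9 rising, with a mean of -0.20 (3.73e-04). Lipid transfer proteins had 15 of 87 falling and 5 rising, with a mean of -0.22 (0.0135), or -0.13 without replicate 1, and the other 7 families did not pass with camera. With fry none of these 9 passed, and MATE efflux proteins did, with 7 of 30 rising, 4 falling and a mean of 0.15 (fry adjusted p = 0.0293; camera adjusted p = 0.153). The sign of each mean of the 9 families past camera's threshold was the same under every alternative setting, but over the alternatives the mean ran from 0.26 to 0.72 for pentatricopeptide repeat proteins, from -0.46 to -0.13 for peroxidases, from -0.36 to -0.14 for receptor kinases and from -0.43 to -0.13 for lipid transfer proteins. None of these 9 held with an estimated correlation (adjusted p = 0.524 for each).

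The copper chaperone CCS, which serves the copper/zinc superoxide dismutases, rose by 1.101 on the log2 scale beside CSD1 and CSD2, and the copper chaperone CCH fell, at -0.78. Neither passed without replicate 1 (limma adjusted p = 0.183 for both, in ranges of 9.54e-04 to 0.183 and 0.00223 to 0.183 over all alternatives) or against a fold of 1.2 (adjusted p = 0.0997 and 0.122). Other genes picked out in the same way were FSD1, at 0.35 but 0.013 with probes averaged, and PETE1, at -0.52. AOX1A, NAC13, CRF6, TIM17-1, UGT74E2 and SOT12 were called higher, at 1.13, 1.78, 1.42, 1.15, 1.68 and 0.79. BCS1, at -0.09, and NDA2, at -0.33, were not called. None of these genes passed without replicate 1 or against a fold of 1.2. Besides ILA, 3 genes changed at least 2-fold on replicates 1 and 2 had the opposite sign on the array labelled replicate 3. NATA1 stood at -2.99, -1.43 and 0.28, AT4G12490 at -2.11, -1.97 and 0.86, and TI1 at -1.38, -1.26 and 0.15. Probes of the plastid genome, by the array file's coordinates, had 33 of 95 higher and 17 lower, and those of the mitochondrial genome 5 of 85 higher and 3 lower. Camera gave an unadjusted p of 0.0604 for the plastid probes and 0.0807 for the mitochondrial ones.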
